A study of Mus musculus with 2 samples.

How the data were processed

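Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts open DNA and inserts sequencing adapters there, in 2 mouse libraries with 1 library per group. Per the labels, the starting cells were marginal zone precursor (MZP) B cells sorted from the spleen of TriB mice, in which NIKΔT3 (an activator of NF-kB) and the intracellular part of Notch2 are switched on from ROSA26 by CD19-cre. The other library, called Bswitch, came from myeloid cells into which transplanted TriB MZPs had converted in some recipient mice. Per the labels' protocols, sorted cells were lysed with NP-40 and digitonin, transposed with a Nextera kit and amplified with 1 index primer per library. The labels name total RNA as the molecule and a transcriptomic source, although the same protocol describes transposed DNA, and the values were treated as ATAC-seq throughout. How many animals gave the cells of each library, and the markers used for sorting, are not given in the sources used here.

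The deposited table holds 79337 peaks that do not overlap one another, from 262 to 5459 bp wide (median 682 bp), and all but 5 carry the symbol of an assigned gene. For each library the table holds a raw count per peak and, as a second column, log2 values made by the authors. The deposited log2 values equal log2 of 1 plus the count per 100000 counts in peaks of that library (largest difference 5.0e-07), with no correction for peak width. The submitters' processing notes name CASAVA, Trimmomatic, Bowtie2, SAMtools, Picard, MACS2, bedtools, featureCounts and ChIPseeker, with the builds GRCm38 and mm10, without versions, order or roles. Whether peaks were called in each library or on pooled reads, whether reads were shifted for the Tn5 cut, how duplicate reads were treated and whether coordinates start at 0 or 1 are not given in the sources used here. Coordinates are printed as deposited. A common peak set lets both libraries be compared peak by peak, but a peak called from the reads of a single library starts with an excess there, most of all where counts are low.

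Counts, not the log2 values, were used for the main comparison. Total counts in peaks were 8639991 for Bswitch and 9625134 for TriB MZP. Library sizes were scaled by TMM factors (edgeR 4.0.16 in R 4.3.3), which were 1.11 for Bswitch and 0.902 for TriB MZP. A count of 1 was added to each scaled count, and ratios are given as log2 of Bswitch over TriB MZP. Peaks with at least 20 counts over both libraries were kept, which left 79153 (99.8%). Because each group has 1 library, no test between the groups was possible and no p-value is given. A peak or gene counts as higher in a library by a size rule, a ratio of 4-fold or more. The 95% intervals of ratios are exact Clopper-Pearson intervals of the share of counts. They cover counting error only, since PCR reads without molecular identifiers are not independent molecules. A ratio against 0 counts was computed against a floor of 3 counts in that library. The nearer bound of its counting interval, which can be lower, is given beside it.

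The value of a gene is the sum of counts over all peaks assigned to it. A promoter peak lies within 1 kb of the 5′ end of its assigned gene in the RefSeq table of GRCm38.p6, with the strand taken from the deposited table. A single 5′ end, that of the gene span, was used per gene. Peaks at start sites further than 1 kb from it were not counted as promoter peaks. Peaks that are not promoter peaks were classed by whether they overlap any RefSeq gene span. Exons, introns and UTRs were not resolved, since the table used gives gene spans only. Of the 18435 gene symbols, 98.3% matched that table.

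Before the data were examined, 16 gene lists were fixed: B lineage, marginal zone B, plasma cell, myeloid core, monocyte and macrophage, neutrophil, dendritic cell, T cell, NK cell, erythroid and megakaryocyte, stem and progenitor, mast cell and basophil, NF-kB response, Notch response, MHC class II and housekeeping. Cr2 stands in the B lineage and marginal zone lists, Dtx1 in the marginal zone and Notch lists, and Csf3r in the myeloid core and neutrophil lists. A list's median log2 ratio has a 95% interval from order statistics over its genes. It was also placed among the medians of 10000 random lists of the same size matched on mean count in 20 bins, as a description of these libraries. The genes named in the text were fixed by a rule: the 10 genes of the most different peaks in each direction among peaks with at least 50 counts and a symbol, up to 4 members of each list with the largest ratio in either direction, and 12 identity genes. Genes named outside this rule are marked as chosen after their values were seen.

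The alternatives were scaling by total counts, by DESeq2 size factors (1.42.0), by counts in the promoter peaks of the housekeeping list or by a loess on mean count; no minimum or a minimum of 50 counts; an added count of 5; 2-fold and 8-fold rules; a rule on the nearer bound of the counting interval; and other ways to sum peaks per gene. The authors' log2 values and a lowess on the number of protein-coding genes within 500 kb were added after seeing the data. A planned comparison of transcription factor motifs was not run, because it needs a genome sequence, which was not used here. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 did the remaining work.

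The size rule was tested on simulated counts for this comparison over 79337 peaks, 200 of them with a known difference. At 2-fold 0 of 50 peaks passed, at 4-fold 23 of 50, at 8-fold 49 of 50 and at 16-fold 50 of 50. Of 78521 kept peaks simulated with no difference, 5 passed. The simulation holds counting error alone, so it says nothing of how much libraries of the same group would differ. Only 200 peaks were changed, as many in each direction, so the scaling was not tested where many peaks differ.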

Results

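Open chromatin was profiled in TriB MZP cells, B cells of the marginal zone precursor stage with active NF-kB and Notch signalling, and in Bswitch cells, the myeloid cells that arose from such B cells after transplantation. The comparison asks how accessibility differs between B cells and the myeloid cells derived from them. Each group had 1 library, with 8639991 counts in peaks for Bswitch and 9625134 for TriB MZP. The median count per peak was 42 in Bswitch and 39 in TriB MZP, and 47 and 241 peaks had 0 counts. No difference below has a replicate check, so each compares these libraries and not the conditions.

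Chromatin at B cell genes was less accessible in the Bswitch library, and chromatin at granulocyte genes was more accessible. Over the 20 B lineage genes the median log2 ratio was −2.74, a 6.68-fold lower value, and 14 of the 20 were at least 4-fold lower in Bswitch while 0 were higher. Over the 17 neutrophil genes the median was 1.70, a 3.25-fold higher value, and 8 of the 17 were at least 4-fold higher in Bswitch while 0 were lower. The antigen presentation genes of the MHC class II list had a median of −1.92. Genes of the NF-kB and Notch responses, the pathways activated in the TriB B cells, also had lower medians in Bswitch, −0.93 and −1.35. Random lists matched on mean count had medians of −0.38 and −0.23, so genes of like counts shared part of these shifts. After the loess on mean count the 2 medians were −0.42 and −0.85.

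Among the 12 identity genes, Cd19 had 37 counts over its peaks in Bswitch and 359 in TriB MZP, a log2 ratio of −3.38 (95% counting interval −3.95 to −2.93). Pax5 and Ebf1, transcription factors that set and hold B cell identity, had ratios of −3.42 (−3.96 to −2.99) and −3.29 (−3.51 to −3.09). Cd79a, a signalling chain of the B cell receptor, had −2.11 over all its peaks and −3.94 at its promoter, and was within 4-fold with total counts (−1.82). Cr2, the complement receptor that is high on marginal zone B cells, had only −0.93 over the sum of its 11 peaks. It had −3.89 at its promoter, with 25 counts against 350. Of the 11 peaks, 8 were at least 4-fold lower in Bswitch and 0 were higher. Cebpa, a transcription factor of granulocyte and monocyte development, had 2.003 (1.83 to 2.19) and 1.43 at its promoter, and Spi1, which encodes PU.1, a factor of both myeloid and B cells, had 1.05 (0.86 to 1.25). Itgam, the CD11b integrin chain of myeloid cells, had 0.78 over all peaks and 2.57 at its promoter. Csf1r, the receptor for macrophage colony-stimulating factor, had −0.94 over its 3 peaks and 1.52 at its promoter (103 counts against 32), so its direction depends on the peaks taken. Ptprc, which encodes the pan-leukocyte antigen CD45, had −0.56 (−0.68 to −0.44).

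Notch2 and Map3k14, the genes whose products the TriB transgenes carry in active form, had ratios of 0.32 (0.22 to 0.43) and 0.82 (0.68 to 0.95). These peaks lie at the native genes, and whether reads from the transgenes add to them was not tested. The promoter peak of the ROSA26 locus that holds the transgenes (chromosome 6, 113076134 to 113077855) had 2128 counts in Bswitch and 1611 in TriB MZP, a ratio of 0.26. This peak was chosen after its values were seen.

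**Figure D1:**
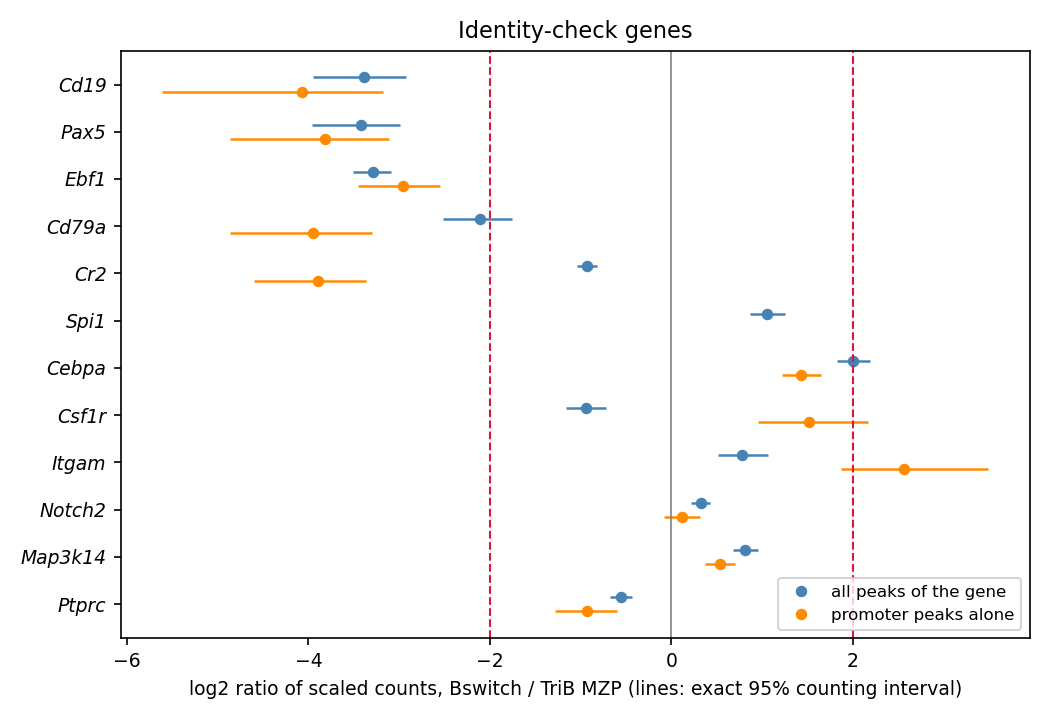
Log2 ratio of scaled counts, Bswitch over TriB MZP (x axis), for the 12 identity genes, over all peaks of the gene (blue) and at promoter peaks alone (orange), with lines for the exact 95% counting interval and dashed lines at 4-fold. Cd19, Pax5, Ebf1 and Cd79a lie below −2 in both measures. Cr2 does so at its promoter but not over the sum of its peaks. Csf1r lies below 0 over all peaks and above 0 at its promoter. Spi1 has no peak that meets the definition of a promoter peak used here, which takes a single 5′ end per gene.

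The B lineage list had an interval of −3.42 to −1.91 for its median, which lay below the medians of all 10000 random lists. Of the 159 kept peaks assigned to its genes, 113 were at least 4-fold lower in Bswitch and 3 were higher. The lowest members were Ms4a1, which encodes CD20 (−4.49, 17 counts against 366), Vpreb3 (−4.16), the B cell Src-family kinase Blk (−3.75) and the Ets factor Spib (−3.72). The number of genes lower was 12 with total counts, 13 with housekeeping promoters or the loess and 15 with the correction for gene density. The marginal zone B list had a median of −0.93 (−2.05 to −0.24, percentile 0.99), with 3 of 12 genes lower. These were Mzb1, an endoplasmic reticulum protein of marginal zone and B1 cells (−4.29), the Notch target Dtx1 (−2.72) and Asb2 (−2.05), and Myof had −1.67. With promoter peaks alone the median was −2.09, with 6 of 10 genes lower and 1 higher. The plasma cell list had −1.33 (−2.13 to 0.16, percentile 0.05), with 2 of 10 genes lower, namely Irf4 (−2.43) and Slamf7 (−2.13). Creb3l2 had −1.50 and Jchain −1.44. With total counts Asb2 (−1.76) and Slamf7 (−1.84) were within 4-fold.

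In the MHC class II list (−3.02 to −1.13 for the median, percentile 0.02), 3 of 9 genes were at least 4-fold lower in Bswitch and 24 of 44 peaks were. Ciita, the master regulator of class II transcription, had 88 counts against 1461 (−4.18). The antigen-presenting chains H2-Aa and H2-Eb1 had −3.02 and −3.01, and H2-Ab1 had −1.998, just under the 4-fold rule. H2-DMb2 had no assigned peak. In the NF-kB list (−1.33 to −0.21, percentile 0.33), 2 of 17 genes were lower, both surface proteins of activated B cells and other antigen-presenting cells: Cd40 (−3.77) and Cd83 (−2.18). The survival gene Birc3 had −1.75 and the inhibitor gene Nfkbie −1.41. In the Notch list (−2.03 to 0.10, percentile 0.03), Dtx1 and the repressor gene Hey2 (−2.03) were lower among 11 genes. The repressors Hes1 and Hes5 had −1.84 and −1.67. With total counts Cd83 (−1.89) and Hey2 (−1.74) were within 4-fold.

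The neutrophil list had an interval of 1.22 to 2.56 for its median, above the medians of all 10000 random lists, and 38 of its 70 peaks were at least 4-fold higher in Bswitch against 4 lower. Fcnb, a ficolin of maturing granulocytes, had 127 counts against 7 (3.87), and S100a8, a subunit of calprotectin, had 242 against 15 (3.79). The primary granule genes Elane and Mpo had 2.67 and 2.57. The number of neutrophil genes higher was 6 of 17 with the correction for gene density and 6 of 10 with promoter peaks alone. By each gene's strongest peak, 7 were higher and 1 was lower. The myeloid core list had a median of 0.72 (−0.16 to 1.08, percentile 99.99). Only Lyz2, which encodes lysozyme (2.497), and Cebpa were at least 4-fold higher among its 21 genes, and 0 were lower. Cebpa was within 4-fold with DESeq2 size factors (1.97), an added count of 5 (1.99) and the correction for gene density (1.70). With promoter peaks alone 5 of 18 myeloid core genes were higher and 1 was lower. Cd33 had 1.71, and Klf4, a factor of monocyte differentiation, had −1.54.

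The monocyte and macrophage list had a median of 0.08 (−0.47 to 1.51, percentile 65.1), and 1.37 when the median was taken over all assigned peaks. Of its 103 kept peaks 42 were at least 4-fold higher in Bswitch and 15 lower. Maf alone, named after its values were seen, held 34 of these peaks, with 23 of the higher and 6 of the lower ones. Pparg (2.53) and Vcam1 (2.05) were at least 4-fold higher among its 18 genes with counts, although their promoters alone had 1.31 and −1.81. Vcam1 was within 4-fold after the loess (1.98) and the correction for gene density (1.88). With total counts 4 genes were higher, and with promoter peaks alone 0 of 16 were higher and 2 lower. The chemokine receptor gene Ccr2, a mark of inflammatory monocytes, had 1.87. Spic, a factor of red pulp macrophages that B cells also express, was lower (−4.30). C1qa, C1qb and Trem2 had no assigned peak.

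Lists of other lineages differed in direction. The mast cell and basophil list had the highest median of the 16 lists, 2.37, with a wide interval over 7 genes (−1.47 to 3.53, percentile 99.1). Its 4 higher genes were the basophil protease gene Mcpt8 (3.53, 164 counts against 12), the mast cell protease genes Cma1 (3.31) and Cpa3 (2.64), and Ms4a2, a chain of the high-affinity IgE receptor (2.37). Fcer1a had no assigned peak. The list did not keep its rank: the median was 0.67 after the loess on mean count, against 1.69 for the neutrophil list, and 1.30 at a minimum of 50 counts, against 1.70. After the loess only Mcpt8 (3.15) and Cma1 (2.21) were 4-fold higher, and Cpa3 had 1.91 and Ms4a2 0.67. The stem and progenitor list had 0.74 (−0.28 to 1.63, percentile 99.7), with the thrombopoietin receptor gene Mpl (2.55) and Cd34 (2.17) higher among 13 genes. After the loess 0 of the 13 were 4-fold higher (Cd34 1.96, Mpl 1.13), and with promoter peaks alone the median was 0.03. Gata2 had 1.63 and Hoxa9 1.29, and Tek had no peak. The erythroid and megakaryocyte list had 0.40 (−0.92 to 1.89, percentile 70.9) and turned to −0.38 with promoter peaks alone. In it Gp9 was higher (2.26) and Hbb-bs lower (−2.42), Gata1 had 1.89 and Pf4 −0.92, and Hba-a1 and Alas2 had no peak. Gp9 was within 4-fold after the loess (1.98) and the correction for gene density (1.93). Hbb-bs, with 7 counts against 38, was within 4-fold with an added count of 5 (−1.95) and was left out at a minimum of 50 counts.

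The T cell list had −0.58 (−1.09 to −0.04, percentile 6.44) over 12 genes and turned to 0.059 with promoter peaks alone. Its members split: Bcl11b, a transcription factor of T cell commitment, had 1096 counts against 82 (3.58, 11 of 14 peaks higher), and the co-stimulatory receptor gene Cd28 had 2.85. Cd3e was lower on few counts (−2.33, 4 against 22), within 4-fold with an added count of 5 (−1.67) and left out at a minimum of 50 counts. Cd5 had −1.63, and Cd3g, Cd8a and Cd8b1 had no peak. The NK cell list had −0.70 (−2.26 to 1.95, percentile 7.92), with Prf1 (−2.29), Il2rb (−2.26) and Klrd1 (−2.17) lower and Ncr1 (2.31, 48 counts against 8) higher among 11 genes. With total counts these 3 lower genes were within 4-fold (−1.99, −1.97 and −1.88), with 2 genes higher and 0 lower. After the loess 0 were higher (Ncr1 1.10) and 4 lower. The dendritic cell list had −0.59 (−1.18 to 0.06, percentile 8.7) and turned to 0.31 when each gene was read from its strongest peak. None of its 10 genes with counts passed 4-fold, but at promoters alone 2 of 6 were lower, by strongest peak 2 were higher and 1 lower, and after the loess 1 was lower. Siglech, a receptor of plasmacytoid dendritic cells, had −1.90 (promoter −2.76), Ccr7 −1.18 (promoter −4.22), Ccr9 −1.17 and Flt3 −0.66, and Cd209a had no peak. The housekeeping list stayed near 0 (−0.08, −0.60 to 0.43, percentile 66.4) and lay slightly above 0 under 3 other scalings, highest at 0.22 with total counts, and lowest at −0.34 with the correction for gene density. All 20 of its genes with counts were within 4-fold, but 1 was 4-fold lower after the loess and 1 with the correction for gene density. Snrpd3 had −1.64 on 12 counts against 36, Sdha −1.26, Emc7 −0.89 and Tbp −0.74, and Vps29 had no peak.

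**Figure D2:**
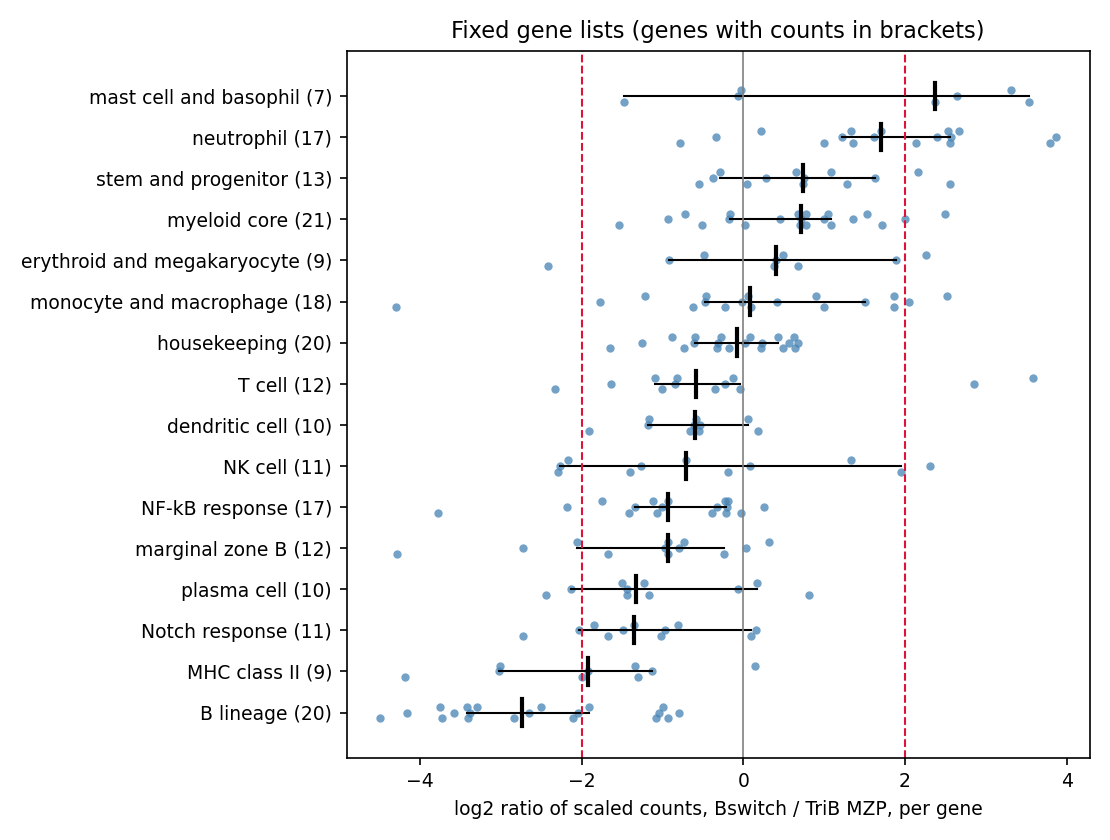
Log2 ratio of scaled counts per gene, Bswitch over TriB MZP (x axis), for the 16 fixed gene lists, ordered by median; points are genes, thick bars medians, thin lines the 95% interval of the median over genes, and dashed lines 4-fold. B lineage (median −2.74) and MHC class II (−1.92) lie lowest and neutrophil (1.70) and mast cell and basophil (2.37) highest, although the last is 0.67 after the loess on mean count and 1.30 at a minimum of 50 counts; the medians of the dendritic cell, T cell, erythroid and housekeeping lists change sign under at least 1 alternative.

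Across the genome, 17661 of the 79153 kept peaks (22.3%) were at least 4-fold higher in Bswitch and 14081 (17.8%) were at least 4-fold higher in TriB MZP. Another 26067 peaks (32.9%) were within 2-fold. Peaks higher in Bswitch made up 55.6% of those past the rule, against 64.1% with total counts, 58.4% with housekeeping promoters, 42.9% after a loess on mean count (11488 higher in Bswitch, 15301 in TriB MZP) and 25.04% with the authors' log2 values (164 and 491). Weak peaks leaned towards Bswitch: at a mean log2 count from 4 to 5 the median ratio was 0.67 and 27.9% of peaks were higher in Bswitch, against 19.2% in TriB MZP. From 5 to 6 the median was −0.25. Below 4 the median was 2.05, with 51.4% of peaks higher in Bswitch and 20.2% in TriB MZP. Weak even peaks are scarce there in the deposited peak set itself, since the minimum of 20 counts kept 79153 of its 79337 peaks. For that reason no lean is read below 4. Even peaks are also scarce just above 4: from 4 to 4.25, 33 peaks had a ratio from −0.25 to 0, against 350 from 1.5 to 1.75. From 4.25 to 4.5 the numbers were 65 and 263. The lean from 4 to 5 may therefore in part reflect which peaks the set holds. At a mean log2 count above 9, 0 of 3790 peaks were higher in Bswitch and 32 in TriB MZP. Summed per gene, 1566 of 18429 genes were at least 4-fold higher in Bswitch and 1241 in TriB MZP. The median ratio of kept peaks was 0.04, and scaling by total counts moved all ratios up by 0.30. A correction for local gene density, added after seeing the data, moved the median to −0.14.

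**Figure D3:**
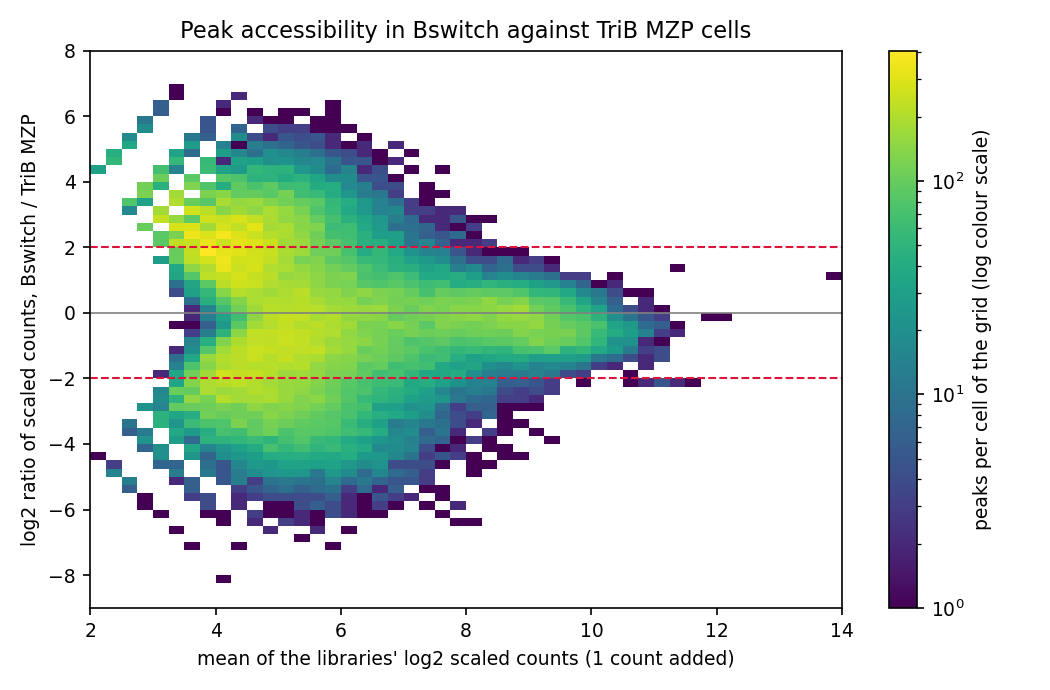
Log2 ratio of scaled counts, Bswitch over TriB MZP (y axis), against the mean of both libraries' log2 scaled counts (x axis) for the 79153 kept peaks, with colour for the number of peaks on a log scale and dashed lines at 4-fold. Peaks at a mean of 4 to 5 lean towards Bswitch (median 0.67) and those at 5 to 6 do not (−0.25). Below 4, and less so just above it, weak even peaks are scarce in the deposited peak set itself. Above a mean of 9 no peak is 4-fold higher in Bswitch.

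Promoter peaks were a smaller share of the peaks that differed than of all kept peaks. Promoter peaks made up 15.4% of all kept peaks, 3.09% of those higher in Bswitch and 7.68% of those higher in TriB MZP. Peaks inside gene spans made up 53.5%, 58.4% and 60.2%, and intergenic peaks 31.1%, 38.5% and 32.1%, in the same order. Promoter peaks were also strong: 10581 of the 12200 kept had 100 counts or more, against a median of 89 over all kept peaks. At a mean log2 count from 8 to 9, 0.25% of peaks were 4-fold higher in Bswitch and 3.14% in TriB MZP. From 6 to 7 the shares were still 9.69% and 20.6%. The shares by position were not matched on strength, so position and strength cannot be told apart here. Among 11863 genes with a kept promoter peak, 504 had a promoter at least 4-fold higher in Bswitch and 1019 in TriB MZP.

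The most different peaks were nearly closed in the other library. Peaks were ranked by the log2 ratio with 1 added to each scaled count, which places peaks with 0 counts in a library high, so the printed folds do not follow the rank. The first in Bswitch lay inside Ank3, which encodes the membrane adaptor ankyrin-G (chromosome 10, 69910051 to 69910900, GRCm38). It had 128 counts against 0, 38.7-fold higher against the floor of 3 counts (nearer 95% counting bound 31.0-fold). A peak inside Glo1, which encodes glyoxalase 1 (chromosome 17, 30609496 to 30610125), had 111 counts against 0, 33.5-fold higher against the floor (counting bound 26.8-fold). The intergenic peak assigned to Actr3, 89.3 kb from its 5′ end (chromosome 1, 125345203 to 125346379), had 536 counts against 5, a 97.2-fold ratio (95% counting interval 41.4 to 300.5). The others in Bswitch were assigned to 3110009F21Rik (221 counts against 1, 200-fold, 35.6 to 7947) and Gjb5 (205 against 1, 186-fold, 32.98 to 7374), and, with 90 to 93 counts against 0, to 4933429O19Rik, Chrm1, H2al1a, Ddhd1 and Fam20c. The first in TriB MZP was an intergenic peak 14.3 kb from Hivep2, a zinc finger transcription factor gene (chromosome 10, 13946389 to 13947293). It had 0 counts against 263, 96.7-fold higher in TriB MZP against the floor (counting bound 78.1-fold). A peak 40.4 kb from B3gat2 (chromosome 1, 23720145 to 23721503) had 4 counts against 693, a 191-fold ratio (74.3 to 704). The promoter peak of the potassium channel gene Kcnq5 (chromosome 1, 21963097 to 21963912) had 6 counts against 633, a 116-fold ratio (53.2 to 318). The remaining peaks were assigned to Inpp4b, Mir3964 (264-fold, 46.9 to 10458), Man1a, Nck2, Kcns2, Pnpla8 and Lingo2, with 0 to 4 counts in Bswitch and 101 to 463 in TriB MZP.

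By chromosome, the median ratio of kept peaks was highest on chromosome 11 (0.41 over 4684 peaks) and lowest on chromosome 13 (−0.42 over 4037 peaks), leaving out chromosome Y with its 13 peaks. At promoter peaks alone these chromosomes were again the highest and the lowest, at 0.20 and −0.89. Among promoter peaks with at least 100 counts, the ratio was higher where more protein-coding genes lay within 500 kb on 20 of 20 chromosomes.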

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

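The authors' log2 values and the correction for local gene density were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The motif comparison and its 4 alternatives were not run. Peaks higher in Bswitch numbered 11488 after a loess on mean count, 11622 with a minimum of 50 counts, 27995 under the 2-fold rule, 7383 under the 8-fold rule and 7274 when the nearer bound of the counting interval had to pass 4-fold. Peaks higher in TriB MZP numbered 25091, 6213 and 7444 under the last 3 rules. With the authors' log2 values 164 and 491 peaks passed, since their added 1 equals 86.4 counts in Bswitch and 96.3 in TriB MZP and pulls weak peaks towards 0. The promoter share of peaks higher in Bswitch was 4.25% under the 2-fold rule and 3.73% at 50 counts, and of those higher in TriB MZP 11.7% and 9.04%. With promoter peaks alone the list medians moved to −3.70 (B lineage), −2.09 (marginal zone B), 1.22 (myeloid core), −1.60 (dendritic cell) and 0.059 (T cell). With each gene's strongest peak they moved to 1.18 (myeloid core) and 0.31 (dendritic cell), and over all assigned peaks to 1.19 (myeloid core) and 0.45 (T cell). The other 167 of 176 list medians under alternatives stayed within the interval of the main median, which includes 0 for 10 of the 16 lists. Chromosome 11 moved to 0.70 with total counts, 0.50 with housekeeping promoters, 0.47 with the loess, 0.25 at 50 counts and 0.20 at promoters, and chromosome 13 to −0.12, −0.24, −0.62 and −0.89 under the same settings without the housekeeping one. Vcam1 reversed to −1.81 at its promoter. The moves of chromosomes 11 and 13 with total counts, and of chromosome 11 with housekeeping promoters, equal the uniform shift of all ratios by these scalings (0.30 and 0.09). Beyond these, the stricter or looser rules and the authors' added 1, the cause was not tested. Of 712 values of named genes under alternatives, 561 stayed within their counting interval, 150 left it and 1, that of Vcam1, turned a 4-fold difference round. Of 160 values of named peaks, 143 stayed within it, 17 left it and 0 turned round. Of peaks past 4-fold, the nearer counting bound also passed it in 15.6% of those with 20 to 49 counts and 81.5% of those with 200 or more.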

Other observations

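The genes and loci in the first 2 paragraphs were chosen after their values were seen, as were the tests on chromosome copy number, T cells, a gain around Bcl11b, the weak-peak trend at Bcl11b, the housekeeping comparison for B cells left, and the correction for gene density. The next genes are some of the 12 in each direction with the most peaks past 4-fold. Bcl11a, a transcription factor of B and plasmacytoid dendritic cells, had 30 of its 31 peaks at least 4-fold lower, with 474 counts against 5471 (−3.67, 95% counting interval −3.81 to −3.54). Bach2, a repressor that restrains plasma cell fate, had 29 of 30 peaks lower (−3.58), and Tcf4, which encodes the E protein E2-2, had 21 of 25 (−3.66). Camk2d, a calcium-dependent kinase gene, and Ext1, a heparan sulfate polymerase gene, had 24 of 25 and 22 of 23 peaks lower (−4.82 and −4.47). Foxp1, a forkhead factor gene, was mixed, with 29 of 85 peaks lower and 14 higher, a gene ratio of −0.47 and a promoter ratio of 0.57. In the other direction Ikzf2, which encodes the Ikaros family factor Helios, had 17 of 25 peaks at least 4-fold higher in Bswitch, with 2132 counts against 354 (2.45, 2.29 to 2.61) and a promoter ratio of 2.04. The sodium and calcium exchanger gene Slc24a3 had 14 of 21 higher (2.49), and the non-coding gene A730004F24Rik 15 of 19 (3.34). Maf, a basic leucine zipper factor gene, had 23 of 34 higher and 6 lower, with a gene ratio of 0.41 and a promoter ratio of −1.38. Fndc3a, Tiam1 and Acvr2a had 16, 16 and 15 peaks higher but gene ratios of −0.03, −0.07 and −0.03. Neighbouring peaks often shared a direction: within 50 kb, the next peak after one higher in Bswitch was also higher in 39.6% of cases, against 21.8% after any peak. For TriB MZP the shares were 38.6% and 17.6%.

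The antigen receptor loci did not share a direction. Over the heavy chain region from the constant genes to the J segments (chromosome 12, 113258768 to 113429833) Bswitch had 373 counts against 1790, a ratio of −2.40 (−2.57 to −2.24), with 9 of 16 peaks at least 4-fold lower. The light chain loci had −2.22 (Igk, 30 of 43 peaks lower) and −2.21 (Igl, 13 of 17 lower). The distal V segments of the heavy chain locus (chromosome 12, 114351705 to 116009954) went the other way, with 15303 counts against 3072, a ratio of 2.17 (2.12 to 2.23), and 47 of 80 peaks at least 4-fold higher against 0 lower. V segments form families of similar copies, so counts of single V peaks are uncertain. DNA copy number over the receptor loci was not measured, so differences in counts there are not read as accessibility alone. The 6 peaks of the D and proximal V segments also leaned to Bswitch, with 284 counts against 88 (1.54, 1.199 to 1.91), 1 of them past 4-fold. The T cell receptor loci had 0.78 (Tcra) and −0.61 (Tcrb) over summed counts, but the median over the 27 peaks of Tcra was −0.08 and over those of Tcrb −1.06. Peaks assigned to Esp38 on chromosome 17 held 0.319% of all counts in Bswitch and 0.122% in TriB MZP.

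Promoter ratios differed between chromosomes, from 0.22 on chromosome 11 to −0.89 on chromosome 13 among promoter peaks with at least 100 counts. A library-wide bias that follows gene density or base composition had what it needs: the ratio was higher at higher local gene density on 20 of 20 chromosomes, with Spearman's rho across promoter peaks, which are not replicates, from 0.168 to 0.583. Correcting for density narrowed the range of chromosome medians from 1.11 to 0.657, with chromosomes 11 and 13 still the extremes at 0.31 and −0.35, so density as corrected here does not account for all of it. Copy number of whole chromosomes cannot be told apart, since the 0.645 (95% bootstrap interval 0.439 to 0.815) by which gene-dense promoters of chromosome 11 exceed gene-poor ones is a gradient that all 20 share. Base composition was not measured, and a difference between the cell types that follows gene density is untested.

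B lineage genes kept different shares of their accessibility in Bswitch, from 4.46% of the TriB MZP level at Ms4a1 to 57.7% at Bank1, named after its value was seen as the list's other extreme. B cells left in the Bswitch cells, as the whole cause, would give every gene the same share, and the counting intervals of 18 of the 20 genes excluded the pooled share of 22.9%. This cause cannot be told apart, because 18 of the 20 housekeeping genes also left their own pooled ratio, so genes differ between these libraries by more than counting error. Peaks of neighbouring genes assigned to the list may raise some members: of the 6 genes within 4-fold, 50% passed 4-fold lower at their promoters alone, 3 of 6, too few to decide. Uneven loss of B cell accessibility during conversion, the biological explanation the design offers, is open and was not tested.

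Bcl11b, a gene of T cell commitment, was 11.99-fold higher in Bswitch. The other 11 T cell genes had a median of −0.815 (−1.63 to −0.04). A large share of T cells among the Bswitch cells would have raised them too, and is argued against. A small share cannot be told, since it could hardly raise genes with many TriB MZP counts. Examples are Gata3 (1004) and Tcf7 (860), named after their values were seen. Cd28 (2.85, 3 of 3 peaks) and 11 Tcra peaks against 4 were higher. A gain of chromosome 12 that takes in the neighbours at higher coordinates is argued against by the promoters of 7 other genes within 1 Mb. Their median was −0.281 (−2.09 to 0.24). All 7 lie on the same side of Bcl11b, from 108178522 to 108894752, so a gain limited to Bcl11b or reaching the other way could not be seen. Whether the lean of weak peaks towards Bswitch is the cause cannot be told. Bcl11b kept a ratio of 3.193 (2.88 to 3.55) after the trend with mean count was removed from each of its 14 peaks. That trend was only 0.51 at their median mean count, so its removal could hardly bring the ratio under 4-fold. Removing it also leaves the spread of weak peaks, 27.9% of which were 4-fold higher in Bswitch at a mean log2 count from 4 to 5. An opening of Bcl11b in the converted cells is a hypothesis found and tested on the same 2 libraries, and other myeloid cells were not compared here.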
